A study of Mus musculus with 4 samples.

How the data were processed

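Ash1 is a trithorax group protein, a histone methyltransferase that acts on chromatin at genes. The series measured where it sits on DNA in V6.5 mouse embryonic stem cells by ChIP-chip: chromatin is broken up, the fragments bound by the protein are pulled down with an antibody, and the recovered DNA is hybridised to an array together with input DNA that was not pulled down. Per the labels' protocols, the cells were grown on irradiated fibroblast feeders and then kept for 2 passages without them, chromatin was sheared to an average of 500 bp, and the DNA was amplified by 2 rounds of ligation-mediated PCR. The immunoprecipitated DNA carried Cy5 and the input DNA Cy3 on all 4 arrays. The arrays were the 2 designs of a mouse promoter set, each hybridised for replicate 1 and for replicate 2. The sample titles number 2 replicates although the series' own design text speaks of single measurements. No source says whether the replicates came from separate cultures. The p-values of single probes therefore measure only the spread between these arrays, which may be technical. The p-values on numbers of probes treat probes as independent and hold no spread between arrays.

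The deposited values are log2 ratios of the 2 channels, 1 per feature and array, with a median of 0 on each array. The log base was not written in the files and was settled from the values: 100.0% of the positive values below 1 lay within 6e-06 of the log2 of a ratio written to 4 decimals, on each of the 4 arrays, while natural logs placed 15.28% to 16.35% there and log10 50.52% to 56.98%. The direction is not stated. Cy5 over Cy3, that is immunoprecipitated over input, is likely, because the labels give the immunoprecipitated DNA as channel 1, and "above 0" and "below 0" are used below with that reading. The scanner, background correction, normalisation and the rule for blank or 0 values are not given in the sources used here. Scanner intensities were not used here, so background correction, other dye normalisations, a filter on dim probes and slide effects were not examined, and the number of arrays, not a depth, limits the precision. No dye swap and no array with a control antibody were among the samples analysed here.

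The deposited tables name features by number. They do not pair these numbers with probe sequences, positions or genes, and neither does the reference used here. The tests planned on genes, on the 27 gene lists fixed beforehand and on the distance to transcription start sites were therefore not run, no gene, region or coordinate is reported, and the tests were made on probes. The place of a feature on the array was computed from its number on a grid of 456 columns and 534 rows. Over lags of 200 to 700 features the correlation of values along the feature number peaked at 456 on 3 arrays and at 457 on design 1, replicate 2.

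Each array was centred on its median, which left the deposited values as they were. The 2 designs hold different probes and each table was analysed alone. For every probe with a value on both arrays of a design, the mean of the 2 log2 ratios was tested against 0 with limma 3.58.1 (lmFit and eBayes, 1 residual degree of freedom per probe, two-sided, Benjamini-Hochberg adjustment over the probes of the design, adjusted p threshold 0.05) in R 4.3.3. This test was run as written before the data were examined, and a second time, chosen after seeing the data, without probes at exactly 0 on either array. In the second run the array medians, and the spreads and quantiles of the alternatives below, were still computed with the zeros in. No array was thus centred anew on the median of the probes tested. On simulated data with 200 changed probes, noise resampled from the differences between the real replicates and the shared zeros as deposited, the first fit recovered 0 of 67 probes changed by 1, 0 of 67 changed by 2 and 0 of 66 changed by 3 on the log2 scale in each design. Without zeros it recovered 14 of 67, 67 of 67 and 66 of 66 in design 1 (203805 probes, 2 false calls) and 2 of 67, 66 of 67 and 66 of 66 in design 2 (196876 probes, 4 false calls). All simulated values came from a common pool of noise, so probes did not differ in their noise. The prior degrees of freedom were 9.665 and 8.716 there, against 6.952 and 5.699 in the real fits without zeros. These recoveries and false calls are thus for probes with more equal noise than the real ones.

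Agreement of the replicates was measured by Pearson and Spearman correlation across probes, by the number of probes past a threshold on both arrays against the number that independent replicates would give, and by the overlap of the highest and lowest 5% of probes (Fisher's exact test, one-sided, 12 tests over designs, sides and cut-offs of 1%, 5% and 10%). Overlap was planned for genes and was run on probes. Probes on a promoter array sample neighbouring DNA, so probes are not independent replicates and these tests describe the arrays. Shares carry exact (Clopper-Pearson) 95% intervals, which cover counting error only. The planned rule for named probes took the 5 with the highest values past the test in each design or, with none past it, ranked by the lower of the 2 replicate values. All 5 are summarised, the first is identified by its feature number, and the lowest probe of each design, by the higher of its 2 replicate values, was added after its value was seen. Alternatives were centring on the mode, equal median absolute deviation, quantile normalisation, robust or trended eBayes, an adjusted p threshold of 0.1, a minimum of 1.5-fold and, added after seeing the data, leaving out zeros and subtracting the median of grid blocks of 18 rows by 19 columns. The trended prior follows the mean log2 ratio of the probe, which is the value under test, and not its intensity. Other calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and plots Matplotlib 3.10.9.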

Results

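Ash1 occupancy of mouse promoters was profiled in embryonic stem cells on 4 arrays, 2 replicates on each of 2 promoter array designs that together make up the promoter set. Design 1 listed 231946 features and design 2 listed 230295. Of these, 220160 and 218326 had a value on both replicate arrays. Blank values made up 1.42% and 3.66% of the features on replicates 1 and 2 of design 1, and 3.43% and 1.77% on those of design 2. In each design, 0 listed features were blank on both arrays, and fewer features were listed than the 243504 grid positions. Whether features blank on both arrays were left out is not known, so these shares hold for the listed features only. Values of exactly 0 made up 7.03% and 5.47% of the values in design 1, and 8.40% and 9.70% in design 2. The standard deviation of the log2 ratio across probes was 0.351 and 0.447 on the 2 arrays of design 1, and 0.374 and 0.413 on those of design 2.

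The comparison made on every array was that of DNA recovered with the Ash1 antibody against input DNA, and the first question was which promoter probes stood away from 0 on both replicates. Above 0 means above input only if the ratio runs as is likely, and with the ratio turned every excess above 0 given here would be one below input. In design 1, 883 probes were at least 2-fold above 0 on both arrays, against 22.8 for independent replicates, and 300 were at least 2-fold below 0 on both, against 36.6. In design 2, 893 probes were at least 2-fold above on both arrays, against 26.5, and 357 below, against 21.6. Probes above 0 thus made up 74.6% (95% interval 72.1 to 77.1) of the probes 2-fold away from 0 on both arrays of design 1 and 71.4% (68.9 to 73.9) of those of design 2. An exact two-sided binomial test against equal numbers gave p = 5.12e-67 and p = 2.27e-53. The test counts probes as independent, which they are not, so it describes these arrays only.

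The excess of probes above 0 was larger at 4-fold. In design 1, 75 probes were at least 4-fold above on both arrays and 1 was 4-fold below. In design 2 the numbers were 110 and 23. At 8-fold, 5 probes of design 1 and 6 of design 2 were above on both arrays, and none was below in either design. Nearer to 0 the balance depended on where the arrays were centred. At a log2 ratio of 0.5, 6266 probes of design 1 were above and 6837 below on both arrays (47.8% above), and 6336 and 6039 of design 2 (51.2%). Centred on the mode of each array, a choice made after seeing the data, the numbers were 5873 and 6788 (46.4%) in design 1 and 4951 and 8009 (38.2%) in design 2.

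**Figure D1:**
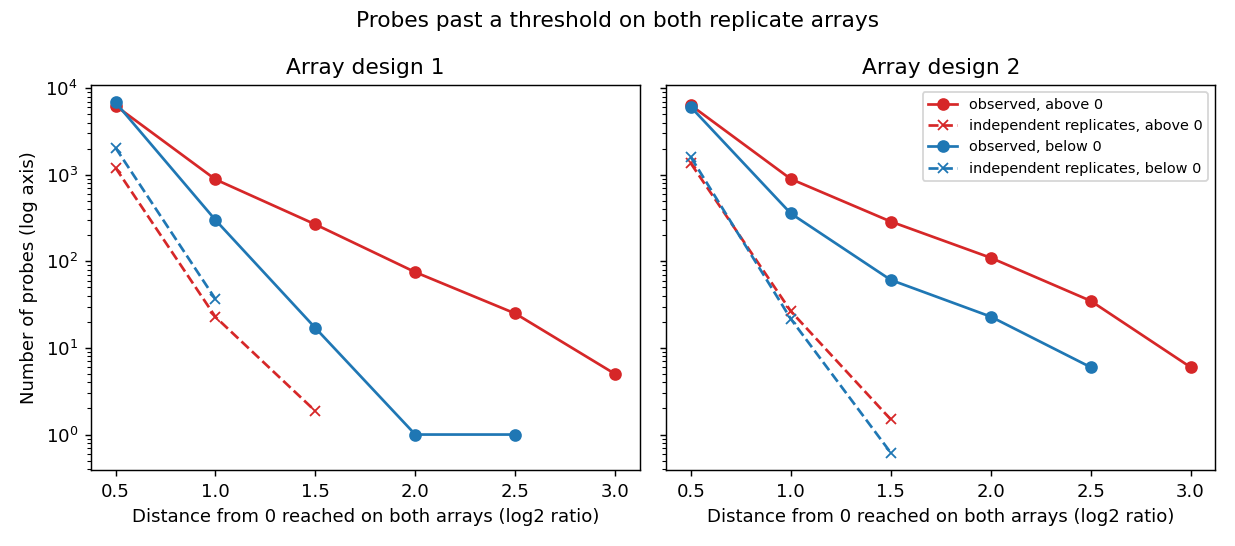
Number of probes (vertical, log axis) at or beyond a log2 ratio (horizontal) on both replicate arrays of each design, above 0 in red and below 0 in blue, with crosses for the numbers expected from independent replicates (drawn from 0.5 probes up). At a log2 ratio of 1 the 883 and 893 probes above 0 exceed the 300 and 357 below.

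At 2-fold, with the values as deposited, the excess above 0 in the probes shared by both arrays was not present on each array alone. Among probes with both values, design 1 had 1819 probes at least 2-fold above and 1627 below on replicate 1, but 2760 above and 4955 below on replicate 2. Design 2 had 2252 above and 1259 below on replicate 1, and 2572 above and 3749 below on replicate 2. In both designs the balance on some arrays turned with the setting. With block medians subtracted, design 1 had 1857 above and 1482 below on replicate 1, and 3150 above and 2318 below on replicate 2. With mode centring, replicate 1 of design 1 had 1606 above and 1969 below. With quantile normalisation, replicate 1 of design 2 had 2401 above and 2467 below. Replicate 2 of design 2 still had 2552 above and 3496 below with block medians subtracted. At 4-fold, more probes were above than below on 3 of the 4 arrays. Design 1 had 200 against 17 on replicate 1 and 303 against 38 on replicate 2. Design 2 had 217 against 51 on replicate 1, but 175 above and 391 below on replicate 2. Of the 200 probes, a single grid block held 41 and the block below it 36. Of these 41 and 36, 0 and 1 were 2-fold above on replicate 2, against 107 of the 159 outside the first block. Of the 391 probes, 91 had another such probe as a grid neighbour, against 4.92 for random places. For the 303 and 217 probes above, these numbers were 4 against 3.05 and 2 against 1.535. Place on the array thus entered the counts of 200 and 391. Of the probes 2-fold above on replicate 1, 48.5% were also 2-fold above on replicate 2 in design 1 and 39.7% in design 2. Of those 2-fold below on replicate 1, 18.4% and 28.4% were also 2-fold below on replicate 2.

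The probe with the highest lower-replicate value in design 1 was feature 137640, with a mean log2 ratio of 3.75 ± 0.65 (SD, n = 2), a 13.4-fold ratio. In design 2 it was feature 21473, with 4.67 ± 0.43 (SD, n = 2), a 25.5-fold ratio. The first 5 probes of design 1 had means between 3.12 and 3.75, and those of design 2 between 3.63 and 4.67. Ranked by the replicate value nearer 0, the lowest probe of design 1 was feature 41123, with a mean log2 ratio of -2.58 ± 0.06 (SD, n = 2), and that of design 2 was feature 56803, with -3.08 ± 0.13 (SD, n = 2). These 2 probes were chosen after their values were seen. The genes and positions of the 4 probes are not known here.

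In the test of each probe against 0, limma called 0 probes in either design at an adjusted p under 0.05. At an unadjusted p under 0.05 it gave 18760 probes above and 19146 below 0 in design 1, and 21008 above and 19398 below in design 2. These balances turned with the setting: a trended prior gave 20875 above and 14549 below in design 1, and mode centring gave 16266 above and 25835 below in design 2. The lowest adjusted p was 0.287 in design 1 and 0.266 in design 2. This fit recovered no simulated change of any size tried, because probes at exactly 0 on both arrays (4655 in design 1 and 10184 in design 2) have a spread of 0, and its count of 0 is no measure of enrichment. Without the probes at exactly 0 on either array, a choice made after seeing the data, limma called 3485 probes above and 3370 below 0 in design 1, and 1755 above and 1003 below in design 2, at the same threshold. The median log2 ratio of the probes called above was 0.96 in design 1 and 1.16 in design 2, and that of the probes called below was -0.88 and -1.05. In that fit the adjusted p from limma was 0.00205 for feature 137640, 0.00402 for feature 21473, 0.00205 for feature 41123 and 0.00429 for feature 56803. With a trended prior the same limma fit called 0 probes in either design and gave these 4 probes adjusted p of 0.868 to 0.962. That prior follows the mean log2 ratio, which is the value under test, and not probe intensity. It is therefore no check of a spread tied to intensity. With replicates scaled to equal spread the fit called 319 above and 20 below in design 1. In design 1 it called 7783 above and 9160 below with mode centring, which put more probes below than above, and 8626 above and 8379 below with block medians subtracted.

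The second question was how far the replicates ranked the same probes. Across probes, Pearson's r was 0.515 in design 1 and 0.514 in design 2, and Spearman's rho was 0.505 and 0.492. Leaving out values of exactly 0, r was 0.536 and 0.534, and 69.8% and 69.1% of probes had the same sign on both arrays. Of the highest 5% of probes of one replicate of design 1, 40.0% were among the highest 5% of the other, 7.996 times the number expected by chance (log10 p = -3029, one-sided Fisher's exact test). In design 2 the share was 34.3%, 6.86 times chance (log10 p = -2237). For the lowest 5% the share was 22.7% in design 1 (4.55 times chance, log10 p = -972.9) and 26.3% in design 2 (5.25 times chance, log10 p = -1310). At the outer 1% the overlap was 41.5 times chance for the highest and 9.04 times for the lowest probes in design 1, and 38.2 and 16.1 times in design 2. With block medians subtracted, a choice made after seeing the data, these were 40.6 and 14.4 times in design 1, and 39.5 and 16.9 times in design 2.

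**Figure D2:**
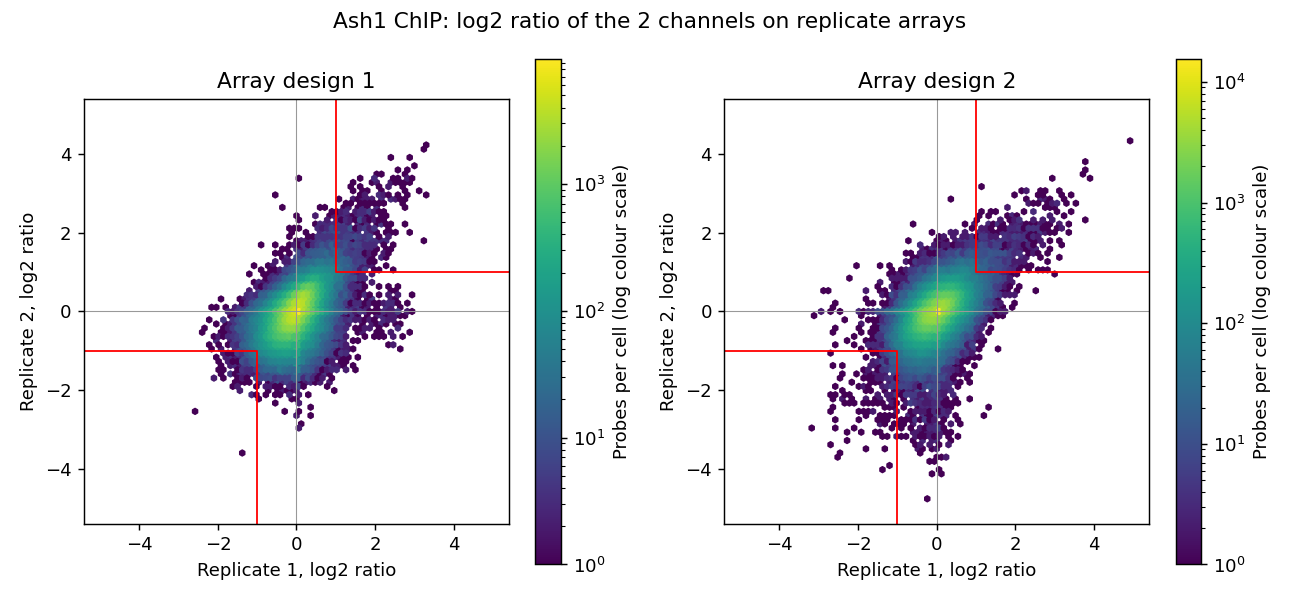
Log2 ratio of every probe on replicate 1 (horizontal) and replicate 2 (vertical) of each design, with colour for the number of probes per cell on a log scale and red lines at a log2 ratio of 1 above and below 0. The upper right corners hold 883 and 893 probes and the lower left corners 300 and 357. A group of design 1 probes lies above 2 on replicate 1 and near 0 on replicate 2.

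Probes chosen on one array and measured on the other give the size of the ratios free of the choice itself. The highest 1% of probes on replicate 1 of design 1 had a mean log2 ratio of 1.33 there and 0.94 ± 0.90 (SD over 2202 probes) on replicate 2. Chosen on replicate 2, they had 1.51 there and 0.90 ± 0.59 on replicate 1. In design 2 the highest 1% had means of 0.92 ± 0.70 and 0.94 ± 0.75 (SD over 2183 probes) on the array that did not choose them. The lowest 1% in design 1 had -0.58 ± 0.47 and -0.28 ± 0.48 on the other array, and in design 2 -0.66 ± 0.66 and -0.44 ± 0.52. These means were not computed with block medians subtracted. On replicate 2 of design 1, that subtraction lowered the number of probes 2-fold below from 4955 to 2318, so place on the array entered the choice of its lowest probes. Place also entered the choice of the highest 1% on replicate 1 of design 1. They held 41 probes of a single grid block, at least 4-fold above on replicate 1, with a median log2 ratio of -0.01 on replicate 2.

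Values also differed with the place on the array. The median over grid blocks ranged from -0.82 to 0.29 on replicate 2 of design 1, with a standard deviation over 720 blocks of 0.169. On the other 3 arrays that standard deviation was 0.055, 0.085 and 0.068. With block medians subtracted, 947 probes of design 1 were at least 2-fold above and 253 below on both arrays, and 900 and 329 in design 2.

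**Figure D3:**
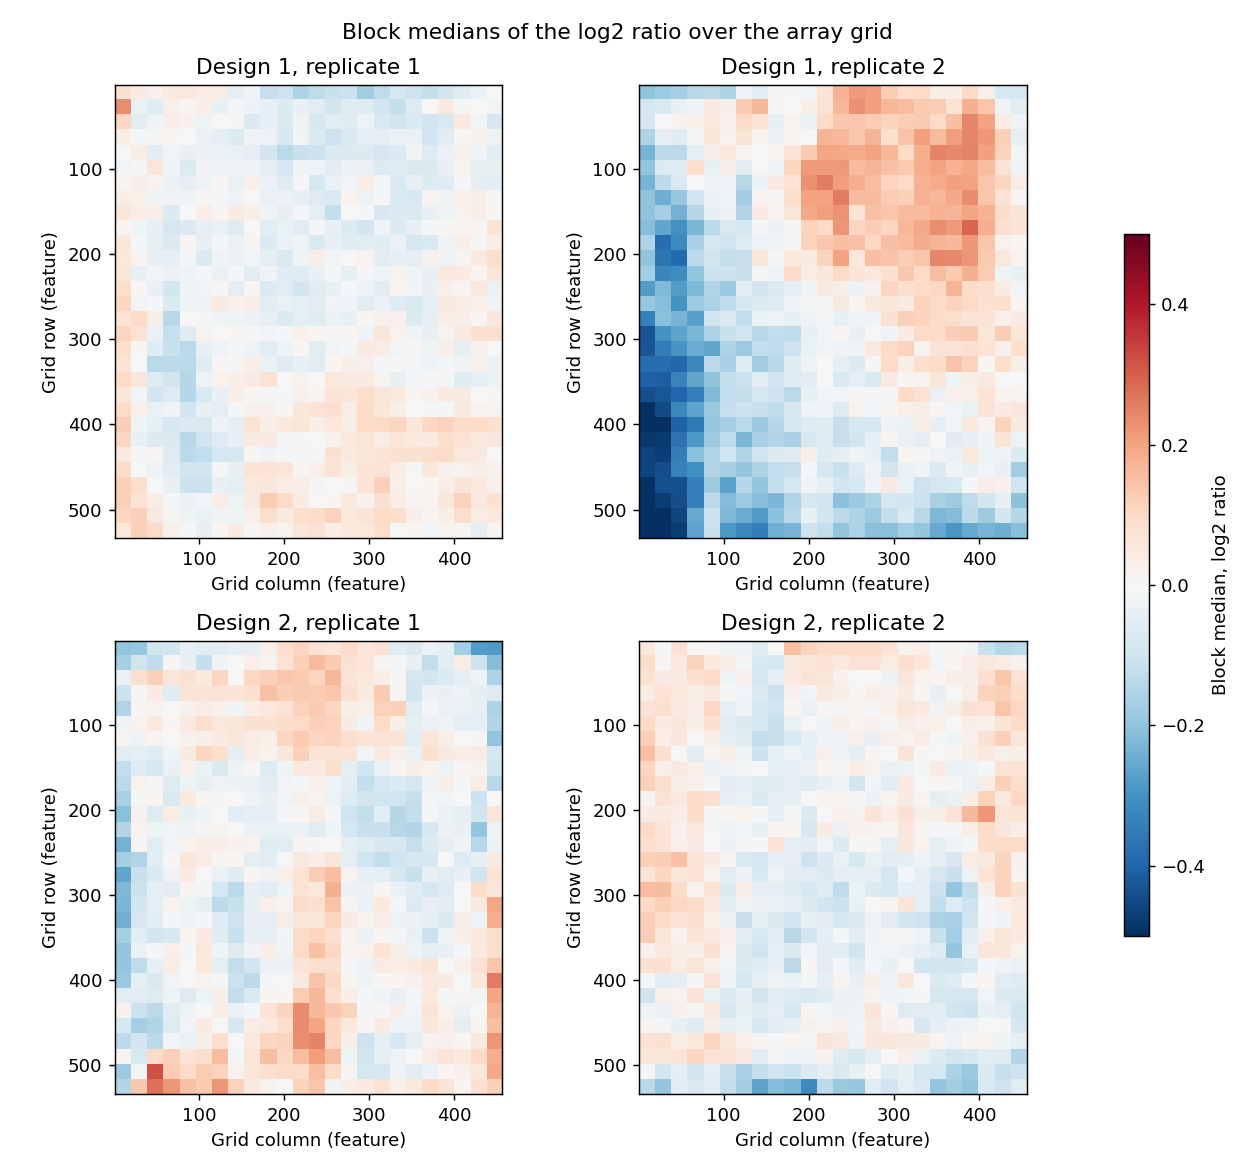
Median log2 ratio in blocks of 18 rows by 19 columns over the grid of each array, values of exactly 0 left out, with red above and blue below 0 and the colour scale ending at 0.5 on either side. Replicate 2 of design 1 falls to -0.82 at its lower left edge and rises to 0.29 towards the upper right.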

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

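The tests on dye and probe bias, on the gradient, on rounding to 0 and on blanks, and the placing of far-off probes, were chosen after the values they concern had been seen. The others were set before their results.

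Values 2-fold away from 0 were also present in probes that no comparison used because they were blank on one array. In design 1, 17 probes were at least 2-fold above 0 on replicate 1 and blank on replicate 2, and 13 were so on replicate 2 and blank on replicate 1. In design 2 the numbers were 9 on replicate 1 and 31 on replicate 2. Each number exceeds the 3 that a count of 0 allows, a bound that noise among so many probes also passes. In the same order, 5, 119, 25 and 44 such probes were at least 2-fold below 0, more than above in all but the first, so these counts do not show signal. The shares above were 0.200%, 0.394%, 0.221% and 0.393% of the probes with 1 value, against 0.826%, 1.25%, 1.03% and 1.18% of the probes with both values on the same arrays.

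The first pattern was the excess of probes above over those below 0 on both replicates. A trend over the array does not account for it: with block medians subtracted, 78.9% (95% interval 76.5 to 81.2) of the probes 2-fold away from 0 on both arrays of design 1 and 73.2% (70.7 to 75.7) of those of design 2 were above. Patches of neighbouring spots do not either, since 2.87% of the probes above on both arrays had another among their 8 neighbours, close to the 2.83% and 2.87% of random places. Dye or probe bias shared by all arrays stays open, because 0 arrays had exchanged dyes or lacked the antibody. Ash1 binding is a possible explanation if the ratio is immunoprecipitated over input, but these arrays could not separate it from such bias, and no biological explanation was tested.

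The second pattern was the gradient on replicate 2 of design 1. If promoters were placed unevenly on the grid, replicate 1 of the same design would show it too, but the block medians of the 2 arrays had a Pearson r of -0.26 (95% interval -0.33 to -0.19). Local effects of this hybridisation or scan stay open. Subtracting block medians raised the correlation between the replicates from 0.515 to 0.573, but with block medians that run against each other it had to rise, and the same holds in design 2, where the block medians had an r of -0.165 and the correlation rose from 0.514 to 0.532.

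The third pattern was that exact zeros fell on the same probes of both replicates, 4655 in design 1 against 501.2 for independent arrays and 10184 against 1145 in design 2. The zeros were at least 689 times as many as the density of values beside 0 gives on each array. That density was taken over a width below the smallest positive value, 0.00014, so the multiple is somewhat too high. Rounding still does not account for the zeros. Place on the array does not account for the sharing, since within grid blocks it was still 11.1 times the independent number in design 1 and 8.66 times in design 2. Probes blank on one array were at 0 on the other at least 16.9 times as often as probes with a nonzero value there, which is consistent with a property of the probe, such as weak signal, that led to a placeholder on both arrays. Without scanner intensities the property itself stays open.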

How the results depend on the processing

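The counts of called probes depended most on the processing. With zeros kept, where 0 probes were called in either design, the count stayed at 0 with equal median absolute deviation, quantile normalisation, robust or trended eBayes and an adjusted p threshold of 0.1. It had to stay at 0 without centring, which repeats the same fit, and with a 1.5-fold minimum, which can only lower a count. The count rose with mode centring in design 1 (9124 above and 11180 below, 0 in design 2) and with block medians subtracted (7053 and 6754 in design 1, 139 and 20 in design 2). The prior degrees of freedom were 1.42 and 0.915 with zeros kept as deposited in designs 1 and 2. They were 32.4 and 1.79 with mode centring, where the modes of the 2 replicates were 0.04 and -0.06 in design 1, which gives all probes at 0 on both arrays one common spread, and 0.05 and 0.05 in design 2. With block medians subtracted they were 7.33 and 3.96. The cause of the calls was not tested further. Without zeros, 3485 probes were called above and 3370 below in design 1, and 1755 and 1003 in design 2. These numbers were the same without centring, which repeats the same fit, and with a 1.5-fold minimum, which every called probe already passed. The corresponding 4 numbers were 7783, 9160, 1242 and 1032 with mode centring, 319, 20, 1490 and 776 with equal median absolute deviation, 1738, 1056, 2007 and 1365 with quantile normalisation, 3130, 2996, 1541 and 817 with robust eBayes, 9273, 10952, 7360 and 7308 at a threshold of 0.1, and 8626, 8379, 1959 and 1225 with block medians subtracted. A trended prior, which follows the value under test, gave 0 for all 4. Of the 6855 and 2758 probes called without zeros, 6752 and 2577 were also called with block medians subtracted. The adjusted p of the 4 identified probes over the settings without zeros ranged from 3.19e-09 to 0.962, the highest values coming from the trended prior. No mean changed sign under any setting, but these probes were chosen for values far from 0, so their signs are no check of the processing.

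The numbers of probes at least 2-fold off on both arrays stayed within 1.5 times their values under mode centring, equal median absolute deviation, quantile normalisation and subtraction of block medians. Mode centring brought design 2 from 893 above and 357 below to 790 and 440. Counted on 1 array alone they were larger by construction, from 1819 to 2760 above and 1627 to 4955 below in design 1, and from 2252 to 2572 above and 1259 to 3749 below in design 2. On replicate 2 alone, as deposited, more probes were below than above at 2-fold in both designs, while at 4-fold this held in design 2 (175 above, 391 below) and not in design 1 (303 above, 38 below). With block medians subtracted, the 2-fold balance of replicate 2 turned in design 1 (3150 above, 2318 below) and not in design 2 (2552 above, 3496 below). Pearson's r between replicates was 0.536 and 0.534 without zeros, 0.573 and 0.532 with block medians subtracted, and 0.593 and 0.553 with both. The overlap of the highest and lowest probes exceeded chance at 1%, 5% and 10%, without zeros and with block medians subtracted. No paired analysis was possible because the 2 array designs hold different probes and are not compared with each other. Other settings named beforehand for probes per gene, gene lists and distance bins were not run, since no gene or position is known for the probes, and leaving out a replicate allows no test.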

Other observations

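All values in this part were computed after the data had been seen. The probes at least 4-fold above 0 on replicate 1 of design 1 lay close together on the array: 79 of 200 had another among their 8 neighbours, against 1.22 for random places. The block at grid rows 19 to 36 and columns 1 to 19 held 41 of them and the block below it, at rows 37 to 54, held 36. Of these 41 and 36, 0 and 1 were 2-fold above on replicate 2. The 41 had a median log2 ratio of -0.01 there against 2.43 on replicate 1, while 107 of the 159 probes outside that block were 2-fold above on both arrays. On replicate 2 of design 2, 91 of the 391 probes at least 4-fold below 0 had such a neighbour, against 4.92 for random places. The 357 probes at least 2-fold below on both arrays of design 2 also lay close together, 49 of them with a neighbour against 3.83 for random places, whereas the 893 above on both arrays did not, with 26 against 25.6.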
